A study of Mus musculus with 32 samples.

How the data were processed

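RNA was measured in mILC1 cells, a mouse mammary tumour line from the K14cre;Cdh1F/F;Trp53F/F model of invasive lobular carcinoma, on 32 two-colour Agilent whole-genome 44K arrays. The arrays form 8 groups of 4 independent samples. Derivatives with doxycycline-inducible hairpins against Foxo1 and Foxo3 (mILC1-shFOXOs in the labels, here shFOXO) were grown with or without doxycycline for 48 h or 72 h, and derivatives with a doxycycline-inducible mutant FOXO3 (mILC1-iFOXO3.A3, here iFOXO3.A3) for 8 h or 16 h. Every sample was hybridised against a common reference of the parental cells. The sample was in Cy5 on 16 arrays and in Cy3 on 16, with 2 of each in every group.

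The deposited scanner files hold, per the file headers, the mean spot intensity and the median local background intensity in each channel, neither background corrected nor normalised. The scanner and the image software were not given in the sources used here. The authors also deposited a table of normalised log2 ratios of sample over reference, whose normalisation is not given in the sources used here. Against log2 ratios of the raw channels, over probes above 1000 units in both, its slope lay between 0.729 and 0.967 on arrays with the sample in Cy5 and between -0.927 and -0.340 on arrays with the sample in Cy3, so its sign is the same for both orientations. Its column medians lay between -0.023 and 0.016. This table served only as an alternative input.

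Each array carried 45220 spots, of which 41174 were gene probes and 4046 control spots. The probe annotation gave a symbol for 34186 probes (83.0%), covering 18322 symbols, and none for 6988. It gave symbols only, some of them since replaced, so genes are named here as the annotation names them. The files state no probe positions, so no coordinates are given. Background was corrected with normexp (offset 50), and intensity trends were removed by loess within each array with control spots given no weight, using limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8). The offset draws the log2 ratios of dim probes towards 0. Probes with a mean log2 intensity above the 40th percentile of all gene probes (6.86) were kept, 24704 in number, 21463 of them named. Each of 13851 genes was represented by its probe with the highest mean intensity. The planned filter on scanner quality marks or labelled negative controls could not be applied because the files hold neither, and the percentile is the substitute set down beforehand. Foxo3 did not pass it and was taken from a fit of all 18322 genes.

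Log2 Cy5/Cy3 ratios were modelled with limma over all 32 arrays, with 1 coefficient per group, signed by orientation, and a dye effect per gene (23 residual and 6.56 prior degrees of freedom). Contrasts were doxycycline minus none at each of the 4 line and time combinations, and the difference of that contrast between the 2 times of each line. P-values are from limma's moderated test, two-sided, adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. Values are given as log2 fold change with the model's standard error (SE), with n = 4 per group. Tests on gene lists used camera with a preset inter-gene correlation of 0.01, adjusted over 84 tests (21 lists in 4 contrasts) or, for the differences between times, over the 21 lists in both lines together, with the result for an estimated correlation beside it. The fry test served to check directions. Some genes are in more than 1 list, so calls on different lists are not independent. Map1lc3b, Gabarapl1 and Bnip3, for example, are in both FOXO-activated targets and the autophagy list. Overlaps between contrasts were tested with Fisher's exact test, two-sided. Correlations of effects are across genes, which are not independent replicates, and carry no p-value.

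The lists, the contrasts and the rule for named genes were fixed before the data were examined. The rule names Foxo1, Foxo3, Foxo4 and Foxo6, the 10 largest rises and 10 largest falls per contrast among genes past the threshold whose 4 induced values all lay on the same side of the 4 uninduced values, and up to 4 members per list with the smallest adjusted p. Where fewer than 2 members passed, up to 2 were given as values only. Names that are only accessions, clones, predicted genes or array codes were left out. Between lines it names the 10 opposite and 10 same-direction genes whose smaller change is largest, and between times the 5 largest differences each way. The text gives part of those the lists contribute.

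Array values carry no counts, so precision rests on the number of arrays and on signal over background. The median sample-channel signal per array lay between 85.3 and 163 units. A probe was called above background where it exceeded the 95th percentile of the 604 copies of a dim control spot, whose design is not given in the sources used here. By that measure 62.7% to 96.3% of gene probes per array were above background, and at most 5 spots per sample channel exceeded 65000 units. Correlations between replicates across genes lay between 0.686 and 0.995.

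The scripts were tested on simulated data with 50 changed genes of each size per contrast among the 13851. At a log2 change of 0.25 they recovered 66% at 48 h, 72% at 72 h, 76% at 8 h and 62% at 16 h. At 0.5 they recovered 98%, 98%, 98% and 100% in the same order, and at 1 and 2 all of them. False calls made up 6.19%, 5.53%, 4.59% and 2.69% of the calls.

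Alternatives tried were no background correction, normexp with offset 10, median centring without loess, an added between-array quantile step, no dim filter, other dim filters, no dye effect, separate fits per line, the mean of all probes of a gene, replicate letter as a block, the authors' values, array weights, a fold threshold, an estimated correlation, other pairs of times and leaving out each sample in turn. A block for slide or scan could not be fitted because the files hold no such column. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.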

Results

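The data are genome-wide RNA profiles of mILC1 cells, a line derived from mammary tumours of K14cre;Cdh1F/F;Trp53F/F mice, in which E-cadherin and p53 are lost. FOXO proteins are transcription factors that growth factor signalling through PI3K and AKT keeps out of the nucleus. The series set hairpins against Foxo1 and Foxo3 beside a mutant FOXO3 in the same parental cells. In the shFOXO derivative, doxycycline switches on hairpins against Foxo1 and Foxo3, and cells were sampled after 48 h and 72 h. In the iFOXO3.A3 derivative, doxycycline switches on a mutant FOXO3, and cells were sampled after 8 h and 16 h. Each of the 8 groups, with and without doxycycline, held 4 independent samples, for 32 arrays in all. No cells with doxycycline and neither construct, and none with a control construct, were analysed here. Effects written below as those of the hairpins or of mutant FOXO3 are therefore effects of doxycycline in that line. Median signals in the sample channel lay between 85.3 and 163 units per array.

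Foxo1 RNA was lowered in shFOXO cells, while Foxo3 RNA could not be followed well on this array. With doxycycline, Foxo1 fell by 1.08 ± 0.06 (log2 fold change, SE, n = 4 per group) at 48 h and by 1.27 ± 0.06 at 72 h, which leaves 47.2% and 41.5% of the uninduced level. A second Foxo1 probe gave -1.13 and -1.29. Neither Foxo3 probe reached the intensity filter, as they stood at the 32.1 and 20.1 percentiles of intensity. The brighter of them gave 0.01 ± 0.04 at 48 h (adjusted p = 0.94) and -0.06 ± 0.04 at 72 h (adjusted p = 0.36), and the dimmer gave 0.05 and 0.06. The sign of the 48 h value turned with the processing, to -0.06 without background correction. In iFOXO3.A3 cells the brighter Foxo3 probe was lower, at -0.12 ± 0.04 at 8 h (adjusted p = 0.020) and -0.11 ± 0.04 at 16 h (adjusted p = 0.041), and whether the probes lie in the part of the message that the transgene carries is not given in the sources used here.

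The other family members changed less in shFOXO cells. Foxo4 read 0.01 at 48 h and 0.03 at 72 h, without passing the test. Foxo6 fell by 0.23 ± 0.08 and by 0.43 ± 0.08. In iFOXO3.A3 cells, Foxo4 rose by 0.23 ± 0.04 at 8 h and 0.38 ± 0.04 at 16 h, and Foxo6 fell by 0.82 ± 0.08 and by 1.30 ± 0.08. Foxo1 read 0.02 ± 0.06 at 8 h (adjusted p = 0.82) and fell by 0.24 ± 0.06 at 16 h. As a list of 3 measured genes, the family was lower at 48 h in shFOXO cells (adjusted p = 0.0494), with an adjusted p of 0.117 with an estimated correlation, and this call held in 5 of 13 other settings. Foxo1, a hairpin target, is among these 3 genes, so the call rests largely on its fall and is no separate result. The list did not pass at 72 h (adjusted p = 0.0562), at 8 h (0.924) or at 16 h (0.818), and at 8 h its median was above 0 and its mean below.

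**Figure D1:**
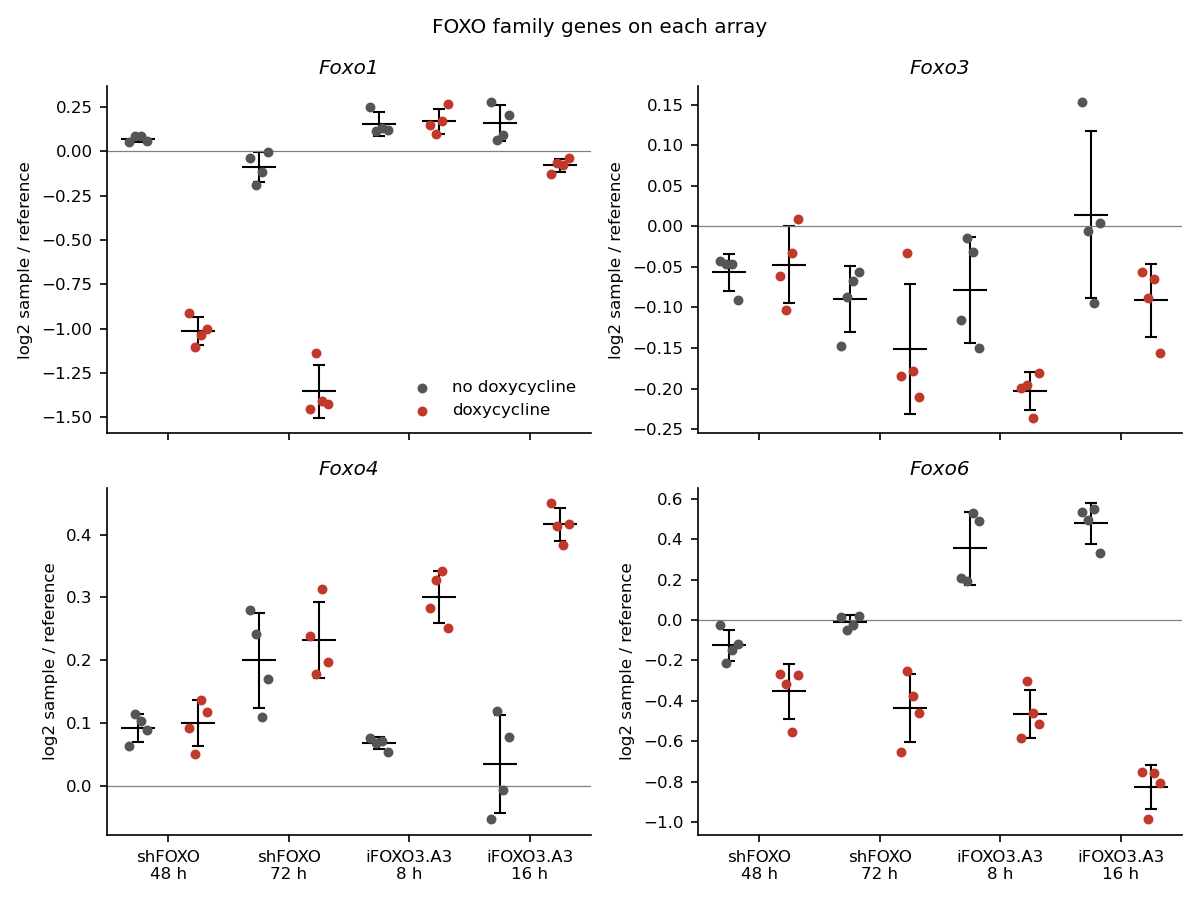
Log2 ratio of sample over parental reference for Foxo1, Foxo3, Foxo4 and Foxo6 on each array, by line and time, without (grey) and with (red) doxycycline; horizontal lines are group means and bars 1 SD of 4 samples, and each panel has its own axis. Foxo1 is separated by doxycycline in shFOXO cells at both times, by -1.08 and -1.27, while Foxo3 values with and without doxycycline overlap there.

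Hairpin induction for 48 h asked what hairpins against Foxo1 and Foxo3 do early. Prl2c3 and Prl2c5, which encode placental hormones of the proliferin group, rose by 2.12 ± 0.17 and 2.05 ± 0.14, and Prl2c1 by 1.93 ± 0.26. Their induced levels stayed below the parental reference, at -1.25, -1.24 and -1.12, and Prl2c3 stood at -3.37 without doxycycline. The neutrophil-attracting chemokines Cxcl5 and Cxcl1 rose by 1.83 ± 0.13 and 1.72 ± 0.10, and Mrc1, a mannose receptor, by 1.85 ± 0.07. Gsta2, a glutathione S-transferase, rose by 1.29 ± 0.10, and Cox11, a cytochrome oxidase assembly factor, by 1.27 ± 0.05. Btg2, an antiproliferative gene, and Herpud1, a gene of endoplasmic reticulum stress, rose by 1.06 ± 0.06 and 1.04 ± 0.05, with other Btg2 probes down to 0.11.

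Among genes named by the rule, the largest fall at 48 h was that of Cks1b, a subunit of cyclin-dependent kinases, by 2.24 ± 0.06. Impad1, a Golgi phosphatase, fell by 1.84 ± 0.06 (another probe at -0.42), Vamp3, a vesicle fusion protein, by 1.73 ± 0.07, and Marcksl1 by 1.60 ± 0.10. Id2, an inhibitor of helix-loop-helix factors, fell by 1.98 ± 0.12 and Rc3h1, which encodes the RNA-binding protein roquin, by 1.87 ± 0.08. Tmem50b fell by 1.90 ± 0.12, Lpgat1 by 1.79 ± 0.09, Snx7 by 1.74 ± 0.08 and Zmat3 by 1.67 ± 0.09. For these last 6 genes another probe on the array read close to 0, at 0.01 for Id2, 0.02 for Rc3h1, -0.11 for Tmem50b, 0.08 for Lpgat1, 0.01 for Snx7 and -0.03 for Zmat3. In all, 3690 of 13851 genes passed the test (limma, adjusted p under 0.05), 1657 higher and 2033 lower, and 88 of them changed at least 2-fold, 11 higher and 77 lower. With arrays only median-centred and not corrected by loess, 326 passed, 73 higher and 253 lower.

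Of the 21 lists, 4 were shifted at 48 h, the FOXO family, which holds the hairpin target Foxo1, and 3 others. Sterol and fatty acid synthesis was lower, with 13 of 24 genes lower and none higher (adjusted over the list alone, 13 and 1; adjusted p = 8.1e-08, and 0.0216 with an estimated correlation). Scd2, a fatty acid desaturase, fell by 1.25 ± 0.10, the sterol enzyme gene Hsd17b7 by 0.61 ± 0.05, Cyp51 by 0.60 ± 0.05 (another probe at -0.04) and Sqle by 0.52 ± 0.04. Autophagy and lysosome genes were higher as a list, with 9 of 23 higher and 2 lower (adjusted over the list alone, 12 and 3; adjusted p = 0.0415, and an adjusted p of 0.289 with an estimated correlation). Lamp2 rose by 0.41 ± 0.05 (another probe at -0.06) and Wipi1 by 0.32 ± 0.05, whereas Map1lc3b, the gene of an autophagosome protein, fell by 0.84 ± 0.06. Integrated stress response genes were higher, with 9 of 22 higher and 2 lower (adjusted over the list alone, 12 and 3; adjusted p = 0.0464, and an adjusted p of 0.480 with an estimated correlation). Chac1 rose by 0.56 ± 0.08 and Mthfd2 by 0.51 ± 0.07, and Trib3 fell by 0.78 ± 0.06 (another probe at -0.15). The autophagy call ended without loess (adjusted p = 0.0564; 0.0212 to 0.289 over all alternatives) and the stress response call when every probe had to exceed background on all 32 arrays (adjusted p = 0.0553; 0.00952 to 0.480 over all alternatives).

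Genes that FOXO factors are known to activate were not shifted as a list at 48 h. Of 38 measured, 6 were higher and 7 lower, the same counts as adjusted over the list alone, with a median of -0.03 (adjusted p = 0.896). Pdk4, a kinase that restrains pyruvate oxidation, rose by 0.98 ± 0.11 and the cell cycle inhibitor gene Cdkn1a by 0.70 ± 0.06, while Bnip3 fell by 0.32 ± 0.04. Among receptor tyrosine kinase and PI3K genes, 2 of 26 were higher and 8 lower (adjusted p = 0.242), with a fall of Met, the hepatocyte growth factor receptor, by 1.46 ± 0.06 (another probe at -0.33). DNA replication had 8 of 36 higher and 6 lower (adjusted p = 0.492), with Ccne2 and Cdc6 falling by 1.04 ± 0.08 and 0.68 ± 0.07. Mitosis had 6 of 32 higher and 9 lower (adjusted p = 0.285). D cyclins and CDK inhibitors had 4 of 18 higher and 5 lower (adjusted p = 0.621), with Cdkn2d and Ccnd1 falling by 1.51 ± 0.08 and 0.64 ± 0.05. Of the other lists, immediate early genes had an adjusted p of 0.0854, interferon response 0.332, oxidative stress defence 0.388, oxidative phosphorylation 0.476, p53 targets 0.476, mesenchymal and matrix genes 0.492, glycolysis 0.897, ribosome biogenesis 0.963 and apoptosis 0.994. For apoptosis, ribosome biogenesis, oxidative phosphorylation and p53 targets the median, the mean and the test differed in sign.

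After 72 h of hairpin induction, the same question was asked of a later state, and more genes had changed. Prl2c5 and Prl2c3 rose by 2.85 ± 0.14 and 2.84 ± 0.17, and Prl2c1 by 2.23 ± 0.26. With doxycycline they still read below the parental reference, at -0.87, -0.94 and -0.80. The chemokine genes Cxcl5, Cxcl1 and Cxcl2 rose by 2.47 ± 0.13, 2.38 ± 0.10 and 2.19 ± 0.11. S100a7a, a calcium-binding protein of inflamed epithelium, rose by 2.39 ± 0.08, Mrc1 by 2.37 ± 0.07, Gsta2 by 2.14 ± 0.10 and the protease inhibitor gene Slpi by 2.13 ± 0.17. Aqp1, a water channel, fell by 2.56 ± 0.15. Of the Ly6 family, which encodes lipid-anchored surface proteins, Ly6c1 fell by 2.29 ± 0.09 and Ly6a fell by 2.26 ± 0.13. Id2 fell by 2.21 ± 0.12, Igfbp4, a binding protein of insulin-like growth factors, by 1.90 ± 0.09, Afap1l2 by 1.88 ± 0.09, Cks1b by 1.87 ± 0.06 and Marcksl1 by 1.86 ± 0.10. Fam162a and Lpgat1 fell by 2.03 ± 0.06 and 1.87 ± 0.09, with another probe reading 0.19 for Fam162a, 0.06 for Lpgat1 and -0.06 for Id2. In all, 5358 of 13851 genes passed, 2622 higher and 2736 lower, and 171 changed at least 2-fold, 49 higher and 122 lower. With median centring alone 923 passed, 400 higher and 523 lower.

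The lists shifted at 72 h were 4 of 21, and none of these calls held with an estimated correlation. Sterol and fatty acid synthesis was lower, with 13 of 24 genes lower and 2 higher, the same adjusted over the list alone (adjusted p = 7.9e-05, and an adjusted p of 0.0969 with an estimated correlation). Scd2 fell by 1.54 ± 0.10, Cyp51 by 0.78 ± 0.05 (another probe at -0.07) and Sqle by 0.57 ± 0.04. Glycolysis was lower, with 10 of 15 lower and 2 higher (adjusted over the list alone, 10 and 3; adjusted p = 0.0171, and an adjusted p of 0.289 with an estimated correlation). Aldoa fell by 0.85 ± 0.08 and the glucose transporter gene Slc2a1 by 0.57 ± 0.06. Integrated stress response genes were higher, with 12 of 22 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.00545, and an adjusted p of 0.315 with an estimated correlation). Chac1 rose by 1.27 ± 0.08, Mthfd2 by 1.22 ± 0.07, the cystine transporter gene Slc7a11 by 1.04 ± 0.09 (another probe at 0.05) and Ddit3 by 0.83 ± 0.07. Mitosis genes were higher by a median of 0.07, with 13 of 32 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.0450, and an adjusted p of 0.602 with an estimated correlation). Kif23 rose by 0.68 ± 0.05 and Nusap1 by 0.60 ± 0.06, with another probe at 0.05 for Kif23 and -0.21 for Nusap1, and the mitosis call held in 8 of 13 other settings.

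FOXO-activated targets divided evenly at 72 h, with 10 of 38 higher and 10 lower, the same adjusted over the list alone, and a median of -0.04 (adjusted p = 0.896). Gadd45b, a stress-induced growth arrest gene, rose by 0.92 ± 0.07, while Map1lc3b fell by 1.18 ± 0.06, Txnip, a regulator of glucose uptake, by 0.87 ± 0.07 and the mitophagy receptor gene Bnip3 by 0.85 ± 0.04. Receptor tyrosine kinase and PI3K genes had 5 of 26 higher and 12 lower (adjusted p = 0.0562), with falls of Met by 1.57 ± 0.06 and of Rictor, a subunit of the TORC2 complex, by 0.65 ± 0.08, for which another probe read 0.06. Among p53 targets, 7 of 14 were higher and 2 lower (adjusted p = 0.0741), with Pmaip1, a proapoptotic gene also in the apoptosis list, rising by 1.66 ± 0.05. In ribosome biogenesis 10 of 25 were higher and 2 lower (adjusted p = 0.0741). Oxidative stress defence had 9 of 28 higher and 5 lower (adjusted p = 0.546), with rises of the thioredoxin reductase gene Txnrd1 by 0.75 ± 0.05 (another probe at 0.03) and of the catalase gene Cat by 0.62 ± 0.06. In the mesenchymal and matrix list, 4 of 24 were higher and 7 lower (adjusted p = 0.621), with Cyr61, a matricellular protein gene, rising by 1.49 ± 0.07. Of the remaining lists, oxidative phosphorylation had an adjusted p of 0.108, autophagy 0.266, D cyclins and CDK inhibitors 0.345, interferon response 0.401, immediate early genes 0.587, apoptosis 0.896 and DNA replication 0.915. The last and the immediate early genes had a median, mean and test of differing sign.

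**Figure D2:**
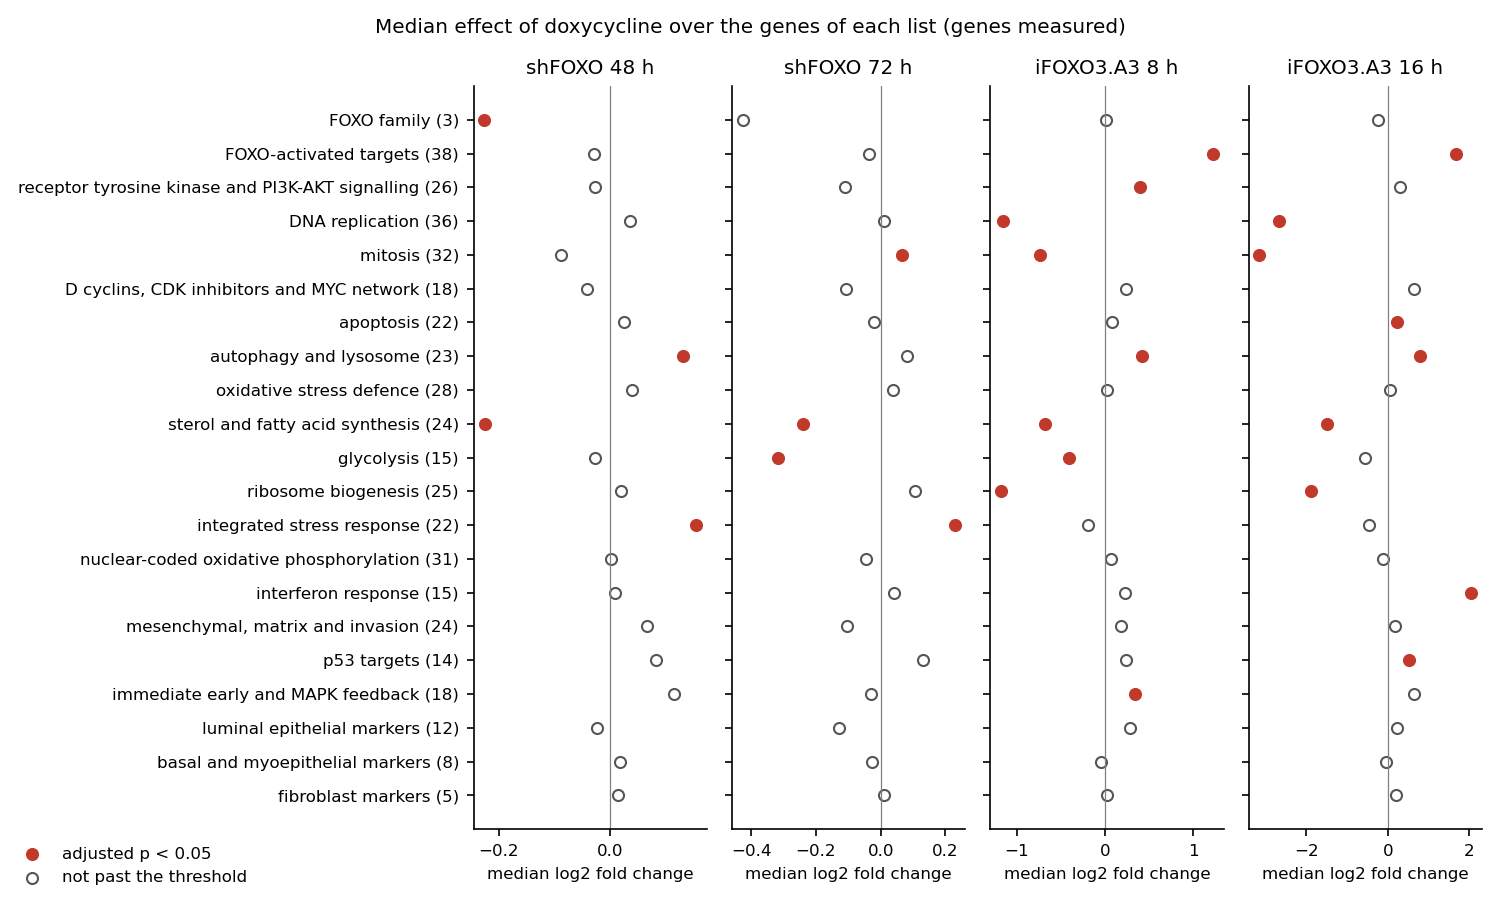
Median log2 fold change (doxycycline over none) of the measured genes of each fixed list in the 4 comparisons, with the number of genes in brackets; filled points passed the list test at an adjusted p under 0.05 and open points did not, and each panel has its own axis. FOXO-activated targets lie at -0.03 and -0.04 in shFOXO cells and at 1.23 and 1.67 in iFOXO3.A3 cells.

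Induction of mutant FOXO3 for 8 h asked which genes respond soon after activation. As lists, FOXO-activated targets rose, and DNA replication and ribosome biogenesis fell. Ctgf, a matricellular growth factor, rose by 4.44 ± 0.09, the transcriptional regulator gene Cited2 by 4.13 ± 0.13, the vasoconstrictor gene Edn1 by 3.83 ± 0.10 and Gadd45a by 3.67 ± 0.08. The kinase gene Sgk1 rose by 3.63 ± 0.10, Rab3b, a GTPase of secretory vesicles, by 3.63 ± 0.13, the collagenase gene Mmp13 by 3.53 ± 0.08, the amino acid transporter gene Slc7a7 by 3.14 ± 0.10, Dyx1c1 by 3.10 ± 0.06 and Trp53inp1 by 3.04 ± 0.13. Another probe read 0.19 for Rab3b, -0.13 for Sgk1, 0.01 for Slc7a7 and 0.14 for Dyx1c1. Rrm2, a subunit of ribonucleotide reductase, fell by 3.39 ± 0.07, the DNA repair gene Ung by 2.71 ± 0.09, Id2 fell by 2.54 ± 0.12, the replicative helicase gene Mcm2 by 2.35 ± 0.04, cyclin D1 (Ccnd1) by 2.33 ± 0.05 and the E2F factor gene E2f8 by 2.32 ± 0.07. Dagla and Bcat1 each fell by 2.39, with SE of 0.08 and 0.07, Oaf by 2.38 ± 0.07 and Pprc1 by 2.32 ± 0.06, with another probe at -0.01 for Dagla, -0.30 for Bcat1 and -0.19 for Id2. In all, 8518 of 13851 genes passed, 4070 higher and 4448 lower, and 973 changed at least 2-fold, 486 higher and 487 lower. Median centring alone gave 4035.

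Of the 21 lists, 9 were shifted at 8 h, and 5 of these calls held with an estimated correlation. FOXO-activated targets were higher, 33 of 38 with 1 lower (adjusted over the list alone, 33 and 2), by a median of 1.23 (adjusted p = 3.0e-15, and 0.00765 with an estimated correlation). Pink1, a mitophagy kinase gene, rose by 2.79 ± 0.08, the receptor gene Erbb3 by 2.50 ± 0.06 (another probe at 0.29) and Map1lc3b by 1.96 ± 0.06. DNA replication was lower in all 36 genes, as also adjusted over the list alone, by a median of -1.16 (adjusted p = 3.3e-20, and 0.00765 with an estimated correlation). Dtl fell by 2.21 ± 0.06 (another probe at -0.08) and Uhrf1 by 2.10 ± 0.06. Ribosome biogenesis was lower in all 25 genes, as also adjusted over the list alone, by a median of -1.18 (adjusted p = 2.8e-14, and 0.0256 with an estimated correlation). Dkc1, Gnl3 and Tsr1 fell by 2.17 ± 0.06, 2.07 ± 0.05 and 2.01 ± 0.06. Autophagy and lysosome genes were higher in 18 of 23, with none lower, as also adjusted over the list alone (adjusted p = 4.8e-06, and 0.0142 with an estimated correlation). Wipi1, Sqstm1 and Gabarapl1 rose by 1.98 ± 0.05, 1.58 ± 0.05 and 1.46 ± 0.04, and Gabarapl1 is also among the FOXO-activated targets. Sterol and fatty acid synthesis was lower in 21 of 24, with none higher, as also adjusted over the list alone (adjusted p = 7.0e-09, and 0.0142 with an estimated correlation), with Sqle falling by 1.66 ± 0.04 and the fatty acid synthase gene Fasn by 1.64 ± 0.06 (another probe at -0.38).

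The other 4 list calls at 8 h were lost with an estimated correlation. Mitosis was lower, with 28 of 32 lower and 2 higher (adjusted over the list alone, 28 and 3; adjusted p = 2.8e-09, and an adjusted p of 0.0717 with an estimated correlation). Ccna2 fell by 1.37 ± 0.06, Nuf2 by 1.21 ± 0.05 (another probe at 0.07), Cdc20 by 1.17 ± 0.05 and Aurka by 1.09 ± 0.05. Immediate early and MAPK feedback genes were higher, 13 of 18 with 3 lower, as also adjusted over the list alone (adjusted p = 0.0104, and an adjusted p of 0.125 with an estimated correlation). Fos rose by 1.86 ± 0.09, Dusp6 by 1.56 ± 0.06, Junb by 1.13 ± 0.08 and Myc by 1.05 ± 0.06. Receptor tyrosine kinase and PI3K genes were higher in 14 of 26 and lower in 7, as also adjusted over the list alone (adjusted p = 0.0245, and an adjusted p of 0.345 with an estimated correlation). Pdgfra rose by 1.80 ± 0.10 (another probe at 0.34), and the PI3K catalytic subunit genes Pik3cb and Pik3ca by 1.38 ± 0.07 and 1.00 ± 0.05. Glycolysis was lower in 11 of 15 and higher in 2, as also adjusted over the list alone (adjusted p = 0.0483, and an adjusted p of 0.387 with an estimated correlation), a call that held in 7 of 13 other settings. Hk2 and Pgam1 fell by 2.06 ± 0.10 and 1.29 ± 0.07.

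Among lists that were not shifted at 8 h, D cyclins, CDK inhibitors and the MYC network had 10 of 18 higher and 5 lower (adjusted p = 0.0562), with Mxi1, a MYC antagonist, rising by 1.86 ± 0.07, Cdkn2b by 1.61 ± 0.06 and Rbl2 by 1.52 ± 0.05. The integrated stress response had 5 of 22 higher and 12 lower (adjusted p = 0.204), with a rise of Chac1 by 2.40 ± 0.08 and a fall of Slc7a5 by 1.51 ± 0.06. Among p53 targets 9 of 14 were higher and 3 lower (adjusted p = 0.160), with a fall of Aen by 2.19 ± 0.06 (another probe at -0.37). Apoptosis genes were higher in 10 of 22 and lower in 4 (adjusted p = 0.224), with rises of Birc3 by 1.01 ± 0.08 (another probe at 0.04) and Bcl2l11 by 0.80 ± 0.07. In the mesenchymal and matrix list, which holds Ctgf and Mmp13, 10 of 24 were higher and 5 lower (adjusted p = 0.0890), with Fn1 rising by 1.58 ± 0.07. Oxidative stress defence had 7 of 28 higher and 10 lower (adjusted p = 0.896), with Sesn3 rising by 2.40 ± 0.10 (another probe at -0.20) and Gclc falling by 1.65 ± 0.06 (another probe at -0.17), and its median and mean differed in sign from the test. Interferon response genes were higher in 8 of 15 and lower in 4 (adjusted p = 0.587), and oxidative phosphorylation in 10 of 31 and 1 (adjusted p = 0.401).

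After 16 h of mutant FOXO3, more genes had changed. The chemokine gene Cxcl3 rose, with raw signals of 64746 to 65285 units on the 4 induced arrays, at or near the scanner's ceiling, so no size is given for it. Ppbp rose by 5.62 ± 0.09 and Cxcl2 by 4.95 ± 0.11. Mmp13, above background on 3 of the 4 uninduced arrays, rose by 5.89 ± 0.08, the interferon gene Ifnk by 5.79 ± 0.10, Rab3b by 5.62 ± 0.13, the peptide hormone gene Calcb by 5.22 ± 0.10, Edn1 by 5.15 ± 0.10, Ctgf by 4.93 ± 0.09 and Tmem140 by 4.93 ± 0.08, with another probe at 1.21 for Rab3b and 0.49 for Tmem140. Birc5, a gene of the chromosomal passenger complex, fell by 4.20 ± 0.07, the mitotic kinase gene Pbk by 4.19 ± 0.07, Rrm2 by 4.17 ± 0.07, Shcbp1 by 3.99 ± 0.06 (another probe at -0.72) and the proliferation marker Mki67 fell by 3.93 ± 0.07. Gtse1 fell by 3.90 ± 0.07, cyclin A2 (Ccna2) by 3.83 ± 0.06, Cdca3 by 3.81 ± 0.07, Aurkb by 3.83 ± 0.10 and Top2a by 3.83 ± 0.08, with another probe at -0.06 for Aurkb and -0.27 for Top2a. Of the 5419 genes with several probes, 561 had probes called in both directions at 16 h, 251 at 8 h, 193 at 72 h and 91 at 48 h. In all, 10404 of 13851 genes passed, 5037 higher and 5367 lower, and 2465 changed at least 2-fold, 1042 higher and 1423 lower.

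The list test called 9 of 21 lists at 16 h, and 5 of these calls held with an estimated correlation. Mitosis was lower in all 32 genes, each by at least 2-fold, with a median of -3.15 (adjusted p = 5.6e-20, and 0.00765 with an estimated correlation). Kif23 fell by 3.76 ± 0.05 (another probe at -0.11), Bub1 by 3.61 ± 0.05 (another probe at 0.22), Cdc20 by 3.57 ± 0.05 and Aurka by 3.46 ± 0.05. DNA replication was lower in all 36 genes by a median of -2.67 (adjusted p = 3.5e-19, and 0.00765 with an estimated correlation), and Mcm2 fell by 3.58 ± 0.04 and Rrm1 fell by 2.91 ± 0.05, for which another probe read 0.07. FOXO-activated targets were higher in 34 of 38 and lower in 2 (adjusted over the list alone, 35 and 2), by a median of 1.67 (adjusted p = 1.0e-12, and 0.0118 with an estimated correlation), with Gadd45a rising by 4.60 ± 0.08, Erbb3 by 2.76 ± 0.06 (another probe at 0.36) and Map1lc3b by 2.61 ± 0.06. Sterol and fatty acid synthesis was lower in all 24 genes (adjusted p = 1.4e-10, and 0.00793 with an estimated correlation), with Idi1 falling by 3.43 ± 0.08 and Sqle by 2.69 ± 0.04. Autophagy and lysosome genes were higher in 21 of 23 and lower in 1 (adjusted p = 1.3e-07, and 0.00765 with an estimated correlation), with Sqstm1 rising by 2.86 ± 0.05 and Wipi1 by 2.76 ± 0.05. For these lists, other than FOXO-activated targets, the counts adjusted over the list alone were the same.

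The remaining 4 list calls at 16 h did not hold with an estimated correlation. Ribosome biogenesis was lower in all 25 genes, as also adjusted over the list alone, by a median of -1.89 (adjusted p = 1.1e-11, and an adjusted p of 0.0522 with an estimated correlation). Dkc1 fell by 2.84 ± 0.06 and Nop56 fell by 2.53 ± 0.06. Interferon response genes were higher in 12 of 15 and lower in 2, as also adjusted over the list alone, by a median of 2.05 (adjusted p = 2.0e-05, and an adjusted p of 0.0717 with an estimated correlation). Oasl2 rose by 4.93 ± 0.11 (another probe at 0.45), Usp18 by 4.09 ± 0.07, Oas1a by 2.75 ± 0.06 and Irf9 by 2.10 ± 0.05. Apoptosis genes were higher in 13 of 22 and lower in 4, as also adjusted over the list alone (adjusted p = 0.0440, and an adjusted p of 0.234 with an estimated correlation). Birc3, which restrains cell death, rose by 1.85 ± 0.08 (another probe at -0.03), and Pmaip1, which promotes it, by 1.61 ± 0.05. Targets of p53 were higher in 10 of 14 and lower in 3, as also adjusted over the list alone (adjusted p = 0.0493, and an adjusted p of 0.289 with an estimated correlation), with rises of Trp53inp1 by 4.07 ± 0.13 and Perp by 1.27 ± 0.06. This last call held in 9 of 13 other settings, and the apoptosis call ended without loess (adjusted p = 0.0664; 0.0239 to 0.234 over all alternatives).

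Of the unshifted lists at 16 h, in D cyclins, CDK inhibitors and the MYC network, 12 of 18 were higher and 4 lower (adjusted p = 0.0532), with Rb1 (another probe at 0.05) and Cdkn2b rising by 2.59 ± 0.07 and 2.15 ± 0.06 and Ccnd1 falling by 2.65 ± 0.05. The integrated stress response had 8 of 22 higher and 13 lower (adjusted p = 0.142), with the serine synthesis genes Psat1 and Phgdh falling by 2.90 ± 0.05 and 2.73 ± 0.06 and Chac1 rising by 3.06 ± 0.08. Glycolysis had 3 of 15 higher and 10 lower (adjusted p = 0.0854), and Ldha fell by 2.53 ± 0.19. Receptor tyrosine kinase and PI3K genes were higher in 13 of 26 and lower in 8 (adjusted p = 0.0916), with Pik3ip1 rising by 2.91 ± 0.13. The mesenchymal and matrix list had 13 of 24 higher and 5 lower (adjusted p = 0.0830), with Fn1 rising by 3.42 ± 0.07 and Timp1 falling by 2.45 ± 0.06. Oxidative stress defence had 11 of 28 higher and 12 lower (adjusted p = 0.896), with Txnip and Cat rising by 2.47 ± 0.07 and 2.08 ± 0.06, and its median differed in sign from its mean and test. Immediate early genes were higher in 11 of 18 and lower in 5 (adjusted p = 0.0854), with a rise of Dusp4 by 2.24 ± 0.06 and a fall of Fosl1 by 1.59 ± 0.08. Oxidative phosphorylation had 9 of 31 higher and 13 lower (adjusted p = 0.896).

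**Figure D3:**
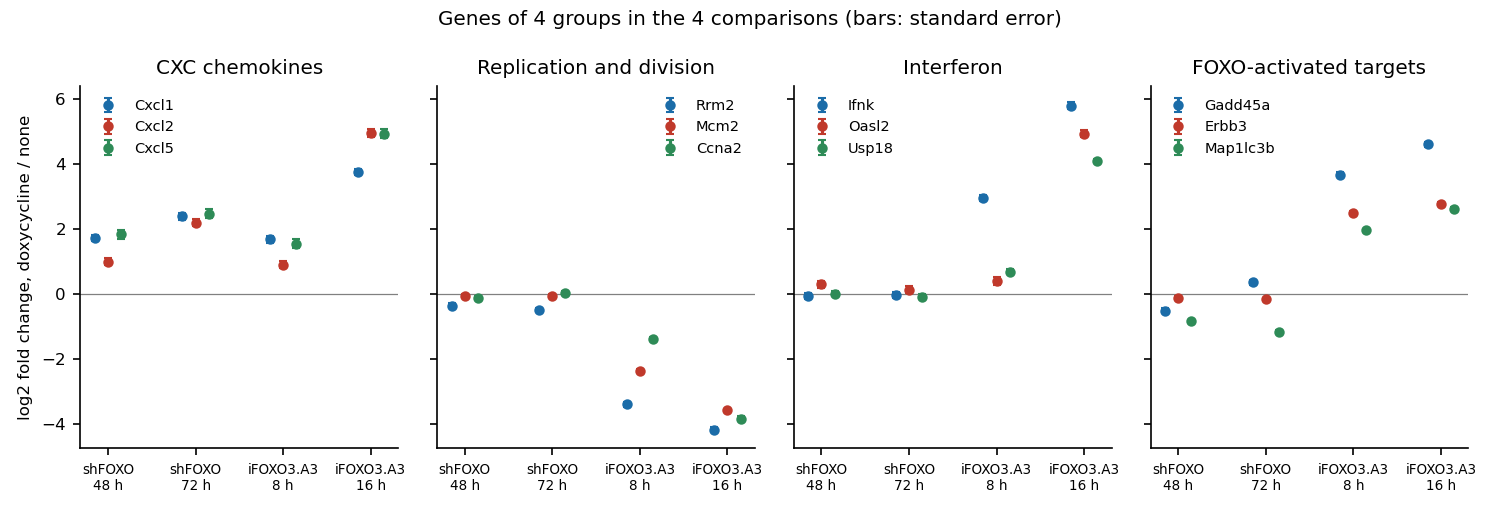
Log2 fold change (doxycycline over none) of 12 genes in the 4 comparisons, with 3 genes in each of 4 groups; bars are the standard error of the fit with n = 4 per group, some smaller than the symbol. Ifnk rises by 2.95 at 8 h and 5.79 at 16 h of mutant FOXO3, Oasl2 by 0.40 and 4.93, and Cxcl1 rises in both lines.

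None of the lists of mammary cell type markers was shifted. Luminal epithelial markers had an adjusted p of 0.924 at 48 h, 0.285 at 72 h, 0.492 at 8 h and 0.257 at 16 h, and of its 12 genes 1, 1, 7 and 8 were higher and 1, 5, 4 and 3 lower in that order. Within that list, Krt7 fell by 0.58 ± 0.11 at 48 h, fell by 0.48 ± 0.11 at 72 h and fell by 0.96 ± 0.11 at 8 h, and Cdh1 rose by 0.66 ± 0.06 at 8 h and 1.05 ± 0.06 at 16 h. Whether the Cdh1 probe lies in the deleted part of the gene is not given in the sources used here. Cldn4 and Krt18 rose by 1.47 ± 0.12 and 0.79 ± 0.05 at 16 h. Basal and myoepithelial markers had an adjusted p of 0.896, 0.671, 0.903 and 0.684 in the same order, with Krt17 falling by 0.34 ± 0.05 and Krt5 by 0.26 ± 0.06 at 16 h. At 48 h those 2 genes read 0.08 and -0.08, without passing the test. Fibroblast markers, 5 genes, had an adjusted p of 0.896, 0.896, 0.546 and 0.457. Pdgfra, which is also in the receptor tyrosine kinase list, read 0.12 and -0.11 in shFOXO cells and rose by 1.80 ± 0.10 and 1.96 ± 0.10 in iFOXO3.A3 cells, whereas Col1a1 read 0.05 at 8 h and rose by 0.29 ± 0.05 at 16 h.

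Whether the response changed with time was tested within each line. In shFOXO cells, the effect of doxycycline differed between 72 h and 48 h for 1059 of 13851 genes (limma, adjusted p under 0.05), 624 in the positive and 435 in the negative direction. The largest positive differences were those of S100a7a at 1.63 ± 0.11, the protease gene Adamts1 at 1.40 ± 0.15, Pmaip1 at 1.31 ± 0.07, the kinase gene Plk2 at 1.30 ± 0.09 and Slpi at 1.24 ± 0.23. The largest negative differences were those of Aqp1 at -1.82 ± 0.21, the calcification inhibitor gene Mgp at -1.81 ± 0.30, the aldehyde dehydrogenase gene Aldh3a1 at -1.54 ± 0.26, Ly6c1 at -1.26 ± 0.13 and Ly6i at -1.16 ± 0.13, and at 48 h Aqp1 and Mgp were above background on 3 of the 4 induced arrays. Without loess 16 genes differed, and without the dye effect 494. The uninduced cells themselves differed between 72 h and 48 h in 4010 genes, and a difference of effects can lie in them. Without doxycycline Aldh3a1 was higher at 72 h by 1.82 and Aqp1 by 1.69, close in size to their differences of effect. Uninduced Pmaip1 read 0.20 against the parental reference at 48 h and -0.40 at 72 h, so part of its difference of effect lies in uninduced cells. For the remaining genes named here the change in uninduced cells is not given.

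In iFOXO3.A3 cells the effect differed between 16 h and 8 h for 6199 genes, 2806 in the positive and 3393 in the negative direction. Here too the uninduced cells differed between the times, in 2466 genes, 1 of them at least 2-fold. Part of a difference of effects can lie in them. Late rises were those of Ppbp, with a difference of 5.03 ± 0.13, the interferon-induced genes Oasl2 and Rtp4 at 4.53 ± 0.16 and 4.32 ± 0.13, Apol9a at 4.14 ± 0.20 and Cxcl2 at 4.04 ± 0.16. Late falls were those of mitotic genes, Cenpa at -3.54 ± 0.11, Cdca3 at -3.29 ± 0.10, Bub1 at -3.28 ± 0.08 and Hmmr at -3.19 ± 0.12, and of Shcbp1 at -3.17 ± 0.09. At 8 h these 5 genes had read 0.17 for Cenpa, -0.53 for Cdca3, -0.32 for Bub1, -0.40 for Hmmr and -0.82 for Shcbp1. At 16 h another probe read -0.01 for Cenpa, 0.22 for Bub1, -0.72 for Shcbp1 and 0.45 for Oasl2. Median centring alone gave 2661 genes, 535 positive and 2126 negative, with the median of all genes displaced to -0.20.

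The effects of the hairpins at 72 h and of mutant FOXO3 at 16 h were then compared gene by gene, since opposite effects would be the simplest relation between them. Across 13851 genes the effects were nearly uncorrelated, with Pearson's r of 0.0750 (jackknife SE over samples 0.0165) and Spearman's rho of 0.0352, and 50.6% of genes had the same sign in both. Of the genes that passed in both, 2156 changed in opposite directions, against 2011 for independent lists, and 2439 in the same direction, against 2014. Genes lower in both were the largest excess, 1377 against 1060 (odds ratio 1.81, Fisher's exact test p = 5.5e-43). Genes higher in shFOXO cells and lower in iFOXO3.A3 cells numbered 1202 against 1016 (odds ratio 1.44, exact p = 2.0e-16), and genes higher in both 1062 against 954 (odds ratio 1.24, exact p = 1.2e-06). Genes lower in shFOXO cells and higher in iFOXO3.A3 cells, the direction in which activated targets would lie, numbered 954 against 995 (odds ratio 0.922, exact p = 0.0724). All contrasts share the same estimate of spread per gene, so a gene of small spread can pass in both without related effects. The counts for independent lists leave this out, and Fisher's test takes genes as independent, so these p-values are only a guide. Over the 38 FOXO-activated targets r was 0.162. The other pairs of times gave r of 0.145 (48 h and 8 h), 0.171 (48 h and 16 h) and 0.0555 (72 h and 8 h), and within a line r was 0.807 for shFOXO and 0.859 for iFOXO3.A3. With median centring alone the opposite count was 259.

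Among genes that changed in opposite directions, Gsta2 rose by 2.14 with the hairpins and fell by 3.01 with mutant FOXO3, and Gsta1 rose by 1.82 and fell by 2.33. Adamts1 rose by 1.65 and fell by 1.90, and Mrc1 rose by 2.37 and fell by 1.40. In the other direction, Afap1l2 fell by 1.88 and rose by 2.10, Rc3h1 fell by 1.47 and rose by 1.76, Ly6c1 fell by 2.29 and rose by 1.30, and Ly6a fell by 2.26 and rose by 1.24. Mgp fell by 1.29 and rose by 3.61, and Ncoa7 fell by 1.27 and rose by 1.56. Genes that changed the same way included 4 chemokine genes, with Cxcl5 rising by 2.47 and 4.92, Cxcl1 by 2.38 and 3.75, Cxcl2 by 2.19 and 4.95 and Cxcl3 by 1.69 with the hairpins, its size with mutant FOXO3 being limited by the scanner as above. S100a7a rose by 2.39 and 2.67 and Pmaip1 by 1.66 and 1.61. Id2 fell by 2.21 and by 2.57, Cks1b fell by 1.87 and by 3.03, Snx7 fell by 1.66 and by 1.84, and Scd2 fell by 1.54 and by 2.96. Another probe read 0.15 and 0.37 for Rc3h1, -0.07 and -0.02 for Snx7 and -0.06 and -0.46 for Id2 in the same order, and -0.26 for Ncoa7 in shFOXO cells.

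**Figure D4:**
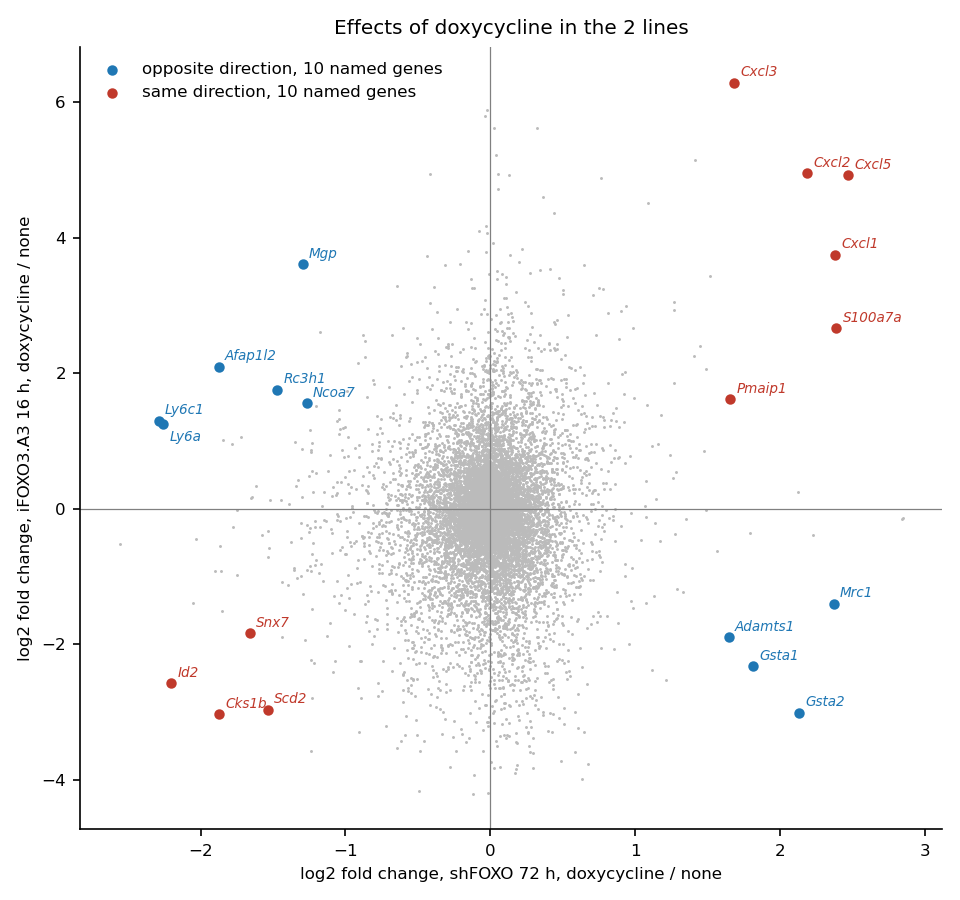
Log2 fold change (doxycycline over none) of 13851 genes in iFOXO3.A3 cells at 16 h against that in shFOXO cells at 72 h, each point a gene; coloured and labelled are the 10 opposite (blue) and 10 same-direction (red) genes with the largest smaller change. The value of Cxcl3 on the vertical axis rests on signals at or near the scanner's ceiling. The cloud shows almost no slope, with r of 0.0750.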

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

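The tests of a doxycycline response, of a direct action of the hairpins and of doxycycline or the vector alone were chosen after the result was seen, and the others were set before it.

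Genes called in both lines pointed the same way more often than independence gives (2439 against 2014), while opposite calls exceeded it by less (2156 against 2011), and over all genes 50.6% had the same sign, with a correlation of 0.0750 (SE 0.0165). Independence leaves out the estimate of spread that the contrasts share. With 48 h in place of 72 h, opposite calls lay below independence, at 1278 against 1381 for 16 h and 1120 against 1129 for 8 h. For 72 h and 8 h they numbered 1906 against 1646. Correlations across dye orientations were 0.0597 and 0.0717. A dye bias constant for a gene cancels between induced and uninduced arrays of the same orientation, so these correlations could not show it. A correlation of 0.0721 after removal of each effect's trend with intensity argues against such a trend. A response to doxycycline shared by the lines stays open, since no cells with doxycycline and neither construct were analysed here. Genes called the same way had a median ratio of sizes (16 h over 72 h) of 2.03 (quartiles 1.12 and 3.63), which decides nothing, because independence gives 2014 of these 2439 genes and the median absolute log2 change over all genes was 0.32 at 16 h against 0.10 at 72 h.

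Among genes changed at least 2-fold after 48 h of hairpins, 77 fell and 11 rose. Faults of single probes as the general cause are argued against by the 63 other probes of the genes that fell that passed the intensity filter. Of these 76.2% were lower, against 13.9% of all probes past the filter. For Id2, Rc3h1, Tmem50b, Lpgat1, Snx7 and Zmat3 another probe read close to 0, as given above, and a fault of the probe stays open there. Were loss of FOXO activity on genes that FOXO raises the cause, the 77 genes should rise more often than others with mutant FOXO3. At 16 h 17 of the 77 (22.1%) rose, against 36.5% of other genes (odds ratio 0.494, Fisher's exact test p = 0.00869), and 50 fell. The prediction was not met, but this does not decide the question. By 16 h 10404 of 13851 genes had changed, so later effects can hide a direct one. A response to doxycycline shared by the lines, left open above, would also move these genes the same way. The falls grew less than the rises, with a median ratio of the 72 h to the 48 h effect of 1.04 against 1.35 (permutation p = 0.00119), and of 1.19 against 2.00 over genes changed 2-fold at 72 h, where the choice of genes works the other way. The permutation took genes as independent, while the 11 rises include the related Prl2c1, Prl2c3 and Prl2c5, Cxcl1 and Cxcl5, and Gsta1 and Gsta2. Its p-value therefore does not measure the spread between samples. A ratio also moves with the uninduced cells, where Mrc1, one of the rises, was lower at 72 h than at 48 h (-1.21). A direct action of the hairpins on these messages is a candidate explanation that these ratios do not settle. The hairpin sequences were not analysed here, and Foxo1 itself had a ratio of 1.17.

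Interferon response genes rose late with mutant FOXO3, with a median difference between 16 h and 8 h of 1.77. Of the 15 genes, 14 were above the dim control spot on all 4 induced arrays at 8 h, which argues against signals too dim to be measured, and the difference without loess was also 1.77. The list had a median of 0.041 in shFOXO cells at 72 h, against 2.05 here. This argues against a response to doxycycline that is alike in both lines and lasts to 72 h. A passing response, or one particular to iFOXO3.A3 cells, stays open. The vector alone could not be tested, because induced and uninduced cells of a line both carry it. The interferon gene Ifnk was higher by 2.95 ± 0.10 at 8 h (adjusted p = 1.3e-21, in 4 of 4 samples), so a secreted interferon made first may contribute, as a hypothesis found and tested on the same data.

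The difference between the 72 h and 48 h effects passed for 1059 genes. Of 100 splits of the samples, 5 gave as many, the real one included, with 1589 as the highest other. These splits exchanged times within induced and uninduced samples separately, so a change with time common to both can enter as a difference of effects. Uninduced cells changed with time in 4010 genes, so chance was neither shown nor excluded for that count. The difference between the 16 h and 8 h effects passed for 6199 genes. Only the real one of 100 splits gave as many (highest other 5061), which argues against chance. Between 72 h and 48 h, 5 lists differed by their medians, mitosis by 0.20, glycolysis by -0.27, ribosome biogenesis by 0.13, integrated stress response by 0.079 and p53 targets by 0.070, and none of these passed with an estimated correlation. Between 16 h and 8 h, 9 lists differed, mitosis by -2.43, DNA replication by -1.21, sterol and fatty acid synthesis by -0.86, autophagy and lysosome by 0.51 and interferon response by 1.77, all of which passed with an estimated correlation, and ribosome biogenesis by -0.46, FOXO-activated targets by 0.30, p53 targets by 0.30 and apoptosis by 0.09, which did not. Without doxycycline, ribosome biogenesis genes were higher at 16 h than at 8 h by a median of 0.37, the largest such change among these 9 lists. Much of the difference of -0.46 can therefore lie in uninduced cells. The largest single differences in shFOXO cells were those of S100a7a (1.63), Adamts1 (1.40), Pmaip1 (1.31), Plk2 (1.30), Slpi (1.24), Aqp1 (-1.82), Mgp (-1.81), Aldh3a1 (-1.54), Ly6c1 (-1.26) and Ly6i (-1.16). In iFOXO3.A3 cells they were those of Ppbp (5.03), Oasl2 (4.53), Rtp4 (4.32), Apol9a (4.14), Cxcl2 (4.04), Cenpa (-3.54), Cdca3 (-3.29), Bub1 (-3.28), Hmmr (-3.19) and Shcbp1 (-3.17).

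Of the 35 splits of the 8 samples of each comparison, only the real one gave as many changed genes. These were 3690 at 48 h (highest other 785), 5358 at 72 h (1198), 8518 at 8 h (4514) and 10404 at 16 h (5903). This argues against chance, but 1 of 35 is the smallest share such splits can give. The other splits mix induced and uninduced samples, and uneven mixtures keep part of the effect, so their counts are not those of chance alone. For the 2156 genes changed in opposite directions, 1 of 100 splits gave as many (highest other 316), but such splits shrink or remove the effects in both lines and say nothing about opposition, for which independent lists give 2011. For the number of lists shifted the 35 splits decide nothing, because uneven mixtures keep part of the effect in the same lists. With the real split counted, as many lists were shifted in 2 of 35 for the 4 at 48 h (highest other 4) and 6 of 35 for the 4 at 72 h (highest other 7). The numbers were 2 of 35 for the 9 at 8 h (highest other 9) and 6 of 35 for the 9 at 16 h (highest other 11). Chance was thus neither shown nor excluded for these list counts.

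Single samples lay far from the other 3 of their group in 4 of 56 groups tested, where chance gives about 1 in 20. They were Foxo3 in replicate d of uninduced shFOXO at 48 h (-0.091, others -0.047 to -0.043), Foxo1 in replicate b of induced shFOXO at 72 h (-1.14, others -1.45 to -1.41), Foxo1 in replicate a of uninduced iFOXO3.A3 at 8 h (0.25, others 0.11 to 0.13) and the percentage of probes above the dim control spot in replicate a of induced shFOXO at 48 h (62.7, others 92.2 to 96.3). Without that last sample 3376 genes passed at 48 h, 1400 higher and 1976 lower.

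Probes without a symbol, which the comparisons leave out, also changed, 546 of 3241 at 48 h, 857 at 72 h, 1536 at 8 h and 2200 at 16 h.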

How the results depend on the processing

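The filter requiring a signal above background on at least 4 of 32 arrays was chosen after seeing the data, and the other alternatives were set before. Median centring without loess changed the counts to 326 genes at 48 h, 923 at 72 h, 4035 at 8 h, 16 for the shFOXO time difference, 2661 for the iFOXO3.A3 time difference and 259 in opposite directions, and there the median of all genes moved to -0.16 at 16 h; the cause was not tested. The shFOXO time difference counted 494 genes without the dye effect and 1628 with array weights, cause not tested. With a fold threshold, a stricter test by construction, 88, 171, 973 and 2465 genes passed at 48 h, 72 h, 8 h and 16 h. With replicate letter as a block the counts were 3811, 5439, 8615 and 10451. An added between-array quantile step left every ratio as it was and tests nothing. It is nevertheless counted among the 13 other settings given for list calls and for Foxo1, and it gave 407 of the 5263 values of named genes below.

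Lists shifted numbered 1 at 48 h, 0 at 72 h, 5 at 8 h and 5 at 16 h with an estimated correlation, 7 at 72 h without a filter and also 7 with a signal above background on at least 4 of 32 arrays, and 2 at 48 h with a signal above background on all 32 arrays, causes not tested. Leaving out each sample in turn gave 1 to 4 lists at 48 h (1 without replicate c of the uninduced group, 2 without its replicate a or b, without induced replicate c or without uninduced replicate b of 72 h) and 3 to 7 at 72 h (7 without induced replicate b). The autophagy call at 48 h ended without uninduced replicate c (adjusted p = 0.0517; 0.0212 to 0.289 over its alternatives), and the mitosis call at 72 h without induced replicate a (0.0574) or uninduced replicate b (0.0704; 0.0214 to 0.602 over its alternatives). With 1 sample left out, the FOXO family call at 48 h held in 14 of 32 fits, the stress response call at 48 h in 26, the glycolysis call at 8 h in 27 and the p53 target call at 16 h in 22.

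Opposite changes numbered 1120 for 48 h and 8 h (1129 for independent lists), 1278 for 48 h and 16 h (1381) and 1906 for 72 h and 8 h (1646). Correlations were 0.145 for 48 h and 8 h, 0.171 for 48 h and 16 h and 0.0555 for 72 h and 8 h. The pair of 48 h and 8 h rests wholly on other samples than the main pair, while the other pairs share its 16 h or its 72 h samples. Foxo3 in shFOXO cells changed sign, without passing in either direction, at 48 h to -0.061 without background correction, -0.052 in the authors' values and -0.0059 with array weights, and at 72 h to 0.0014 with the mean of all probes. Values near 0 also changed sign for Foxo4 at 48 h, to -0.013 with median centring and -0.0043 with array weights, and with the mean of all probes for Foxo1 (-0.033) and Col1a1 (-0.019) at 8 h; causes were not tested. With 1 sample left out, Foxo3 at 48 h ranged from -0.010 (without induced replicate d) to 0.029, Foxo4 at 48 h from -0.0054 (without induced replicate c) to 0.024 and Foxo1 at 8 h from -0.016 (without induced replicate d) to 0.051.

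Foxo1 fell under all 13 alternatives run for it, and with 1 sample left out lay between -1.12 and -1.05 at 48 h and between -1.34 and -1.23 at 72 h. Gene counts with 1 sample left out ranged from 3165 to 3886 at 48 h, 4860 to 5515 at 72 h, 8092 to 8691 at 8 h and 10053 to 10428 at 16 h. Of 5263 values of the named genes under other settings, which leave out Foxo1 and Foxo3 in shFOXO cells given above, 5116 kept direction and side of the threshold, 141 fell short of it (96 of them with median centring), 2 newly passed and 4 changed sign. A block for slide or scan was not run, because the files name none. The Foxo3 probes were dim, at the 32.1 and 20.1 percentiles of intensity, and above background on 30 and 27 of 32 arrays.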

Other observations

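All values in this part were chosen after they were seen, and none was tested as an explanation. Uninduced cells differed from the parental reference at least 2-fold in 278 genes for shFOXO at 48 h (21 higher, 257 lower), 192 at 72 h (22 and 170), 62 for iFOXO3.A3 at 8 h and 54 at 16 h. Prl2c3 was lower than in the reference in all 4 uninduced groups, by log2 values of -3.37, -3.78, -4.49 and -4.63 in that order, and in uninduced shFOXO cells Tmsb4x read -3.74 and -3.94 and Afp 3.17 and 2.96.

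The uninduced shFOXO groups differed from each other in 4010 genes between 72 h and 48 h, 39 of them at least 2-fold (37 higher and 2 lower at 72 h). Txnip was higher by 2.49, Aqp1 by 1.69 and Mgst1 by 1.61, and Mrc1 was lower (-1.21). Ribosome biogenesis genes were lower by a median of -0.45 and FOXO-activated targets higher by 0.23, and these signs were the same with median centring (-0.40 and 0.27) and in the authors' values (-0.49 and 0.25). Between the uninduced iFOXO3.A3 groups at 16 h and 8 h, ribosome biogenesis genes were higher by 0.37, with median centring by 0.76 where the median of all genes moved to 0.25.

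Of 8 CXC chemokine genes, 4 were higher at 48 h, 7 at 72 h, 6 at 8 h and 6 at 16 h, and 0, 0, 1 and 2 lower; with median centring 3, 6, 6 and 6 were higher and the same numbers lower. Within the interferon list at 16 h, Isg15 read 2.48, Irf7 2.05 and Gbp2 3.20, while Cxcl10 read -1.46.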
